A study of Mus musculus with 6 samples.

How the data were processed

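RNA was measured in 6 samples of mouse pancreatic ductal adenocarcinoma (PDAC) organoids, 3 transduced with a control short hairpin RNA (shRNA) and 3 with a lentiviral shRNA against Jag1 (the hairpin numbered 3). Organoids are clusters of tumour cells grown in gel in a defined medium, here with EGF, FGF-10, gastrin, R-spondin-1 and Noggin per the labels' protocols. Total RNA was turned into libraries with an Illumina TruSeq RNA kit, per the labels' protocols, which does not mark the strand of the transcript. Reads of a gene and of a gene that overlaps it on the opposite strand therefore cannot be told apart.

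The submitters' processing notes list Trimmomatic, STAR 2.5.2b, DESeq2 1.32.0 and the genome build GRCm38. Neither the counting tool nor the annotation is stated. The deposited values are normalised counts, a signal per gene and library in which the authors divided the read counts by 1 size factor per library. This was checked on the values: within 0.001 of a read, 100% of the values of each library were whole multiples of 1 step, so the whole reads could be recovered. The size factors equal the median-of-ratios factors of DESeq2 computed over all features of the table, spike-ins included. All 6 deposited tables were identical, each holding the 6 libraries, and 1 was used and 5 were left out as copies. The table listed 14302 features, of which 48 were ERCC spike-in RNAs and 14254 were genes. The lowest total of a listed feature was 61 reads over the 6 libraries, and the rule by which features were left out is not stated. Ensembl gene identifiers were matched to symbols and to GRCm38 positions of GENCODE release M21 for 14219 genes, and 35 identifiers stayed without a symbol.

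Groups were taken from the sample titles. All choices of test, gene lists, named genes and alternatives were made before the data were examined, except where stated. The test was limma-trend (limma 3.58.1 in R 4.3.3) on the log2 of the normalised count plus 1, for the 13997 genes with a normalised count of at least 10 in at least 3 samples, with Benjamini-Hochberg adjustment and a threshold of 0.05. The filter left out 257 genes. No covariate entered this fit, since the labels state no pairing. Reported log2 changes are knockdown minus control, with the moderated standard error (SE). The spike-ins entered no test of genes. For Jag1 an exact two-sided permutation test was also run, which for 3 against 3 samples cannot give a p below 0.1, and an exact sign-flip test over the 3 pairs, which cannot go below 0.25.

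The replicate numbers were checked for pairing before calls were compared. The deviations of the log2 values from the group means correlated across genes at r = 0.68, r = 0.57 and r = 0.44 for libraries with the same number 1, 2 and 3, and each library correlated best with its own number. The labels do not say what a number stands for, and by the threshold of 0.1 for every pair the numbers were treated as pairs. Control 3 with knockdown 2 (r = 0.385) and control 2 with knockdown 3 (r = 0.365) passed it too. The threshold thus does not tell pairs 2 and 3 from their swap. On the log2 values themselves, control 2 was closer to knockdown 3 (r = 0.949) than to knockdown 2 (r = 0.946). Where the fit with the replicate number as a term of the model (the blocked fit) changed a call, its value is given beside the result.

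A total of 29 gene lists were fixed before the data were examined, and 24 with at least 5 tested members were compared with all other genes by camera in limma with a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 24 lists. The tested lists were Notch targets, Notch components, epithelial, mesenchymal, partial EMT (epithelial-mesenchymal transition), tumour-initiating cell markers, ductal, classical PDAC, basal-like, tuft cell, proliferation, p53 targets, interferon, antigen presentation, NF-kB and inflammation, Wnt targets, TGF-beta targets, YAP targets, MAPK targets, unfolded protein response, hypoxia and glycolysis, cholesterol synthesis, NRF2 targets and tetraspanins. The acinar, endocrine, fibroblast, immune and endothelial lists had 3, 1, 3, 3 and 4 tested members and were described by gene. The lists share members: 29 of their 598 genes stand in more than 1 list. Each list test was repeated with a correlation estimated from the data and with fry. With a preset correlation camera takes its degrees of freedom from the number of genes, and with an estimated one from the libraries.

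The genes named in the text followed a fixed rule. It took Jag1, then 14 genes of interest (Cd9, Cdh1, Epcam, Vim, Zeb1, Hes1, Hey1, Nrarp, Jag2, Dll1, Dll4, Notch1, Notch2 and Notch3). It took the 12 genes with the largest change in each direction among called genes with a mean of at least 50 in the higher group and groups that did not overlap, without pseudogenes, predicted genes and clone names. From each list it took up to 4 called members with the largest change, or the 2 members with the highest mean where none was called, and it took the members of any count of 5 or fewer. The limma fit called no gene, so after that result was seen the same rule was applied a further time to DESeq2 1.42.0 on the recovered whole reads with the replicate number as a term, again with an adjusted p below 0.05. Log2 changes and SEs of single genes are those of that DESeq2 fit unless limma is named. A few genes that the rule or a count of 5 or fewer would name are left out of the text, so some counts below name only part of their genes.

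The alternatives fixed in advance were a pseudocount of 0.5 and of 5, no filter, a filter at 50, quantile normalisation, median centring, limma without a trend, edgeR 4.0.16 quasi-likelihood with TMM factors on whole reads, DESeq2 without the replicate term, the limma replicate block, and leaving out each library in turn. Where that left a group with 2 samples the spread was pooled across both groups. Chosen after the data were seen were DESeq2 and edgeR with the replicate term, DESeq2 with the replicate term leaving out each pair, limma on replicates 2 and 3 only, limma with a term for replicate 1 against the others, camera in the blocked fit with an estimated correlation, and scaling by the ERCC reads. Adjusting genes over the members of 1 list alone was not among the choices fixed in advance either. That adjustment does not correct for the number of lists or for the other genes.

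Each fit was tested on simulated data. Counts were drawn for each of the 13997 genes independently, from the real library sizes and from fitted means with replicate effects and no knockdown effect. Then 100 genes were changed by 2-fold and 100 genes by 4-fold, alike in every pair. Without the replicate term limma recovered 0 and 22 of them with 0 false calls, edgeR 0 and 17 with 0 false calls, and DESeq2 17 and 87 with 0 false calls. With the replicate term limma recovered 63 and 98 with 6 false calls, edgeR 61 and 99 with 6 false calls, and DESeq2 76 and 99 with 33 false calls. The real knockdown differences were unlike between pairs, so these counts do not give the share of false calls in the real data.

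The recovered reads came to 30515717, 24188827 and 22268997 in control libraries 1, 2 and 3, and to 29824152, 23219455 and 35172593 in knockdown libraries 1, 2 and 3. A single read was worth between 0.764 and 1.25 normalised counts. Between 2 libraries of the same group, the squared difference of a gene's reads was on average 18.3 to 311 times that of counting error. Exons of 16 of the 127 named genes share bases with another gene of the table in GENCODE M21, and in 4 of them, Prap1, Ccnd1, Ccn2 and Ankrd37, over 20% of the exon bases are shared with a gene on the opposite strand. Sprr2a3, Gsta1, Tdpoz4, Teddm3 and Ly6g belong to families of near-identical genes, so their counts are uncertain. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.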

Results

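The data describe gene expression in organoids of a mouse pancreatic ductal adenocarcinoma (PDAC) line, KPF_5.3G, measured by RNA sequencing of total RNA. Organoids carried either a control shRNA (3 samples) or an shRNA against Jag1 (3 samples), a transmembrane ligand of the Notch receptors. The design sets both groups against each other to ask what Jag1 does in tumour-initiating cells that are high in the tetraspanin CD9 and express epithelial and mesenchymal genes together, a hybrid state of the epithelial-mesenchymal transition (EMT). The libraries held 30515717, 24188827 and 22268997 reads in controls 1, 2 and 3, and 29824152, 23219455 and 35172593 reads in knockdowns 1, 2 and 3. Values are normalised read counts, given as the mean ± SD of 3 replicates, and log2 changes are knockdown minus control. In a fit without the replicate term, an adjusted p of a gene measures the difference against the spread of these 3 libraries per group. With the term, it measures the difference against the spread left once differences between replicate numbers are taken out. The p of camera sets a list against all other genes.

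Both replicate 1 libraries separated from the other 4 before libraries separated by group. The other 4 were closer by group than by number on the log2 scale. Control 2 and knockdown 2 correlated at r = 0.95 across genes, as did control 3 and knockdown 3. The first principal component held 55.8% of the variance of the log2 values and set both replicate 1 libraries apart from the other 4, and the second held 29.0% and ordered knockdown above control within each replicate number. Across genes, control 1 and knockdown 1 correlated at r = 0.99 on the log2 scale, controls 2 and 3 at r = 0.99, and knockdowns 2 and 3 at r = 0.98, whereas control 1 and control 2 correlated at r = 0.91. The SD of the log2 difference between knockdown and control across genes was 0.47 in pair 1, 0.92 in pair 2 and 0.86 in pair 3. Differences of pairs 2 and 3 correlated across genes at r = 0.74, and those of pair 1 correlated with pairs 2 and 3 at r = 0.27 and r = 0.14. Genes are not independent replicates, so these correlations carry no p.

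**Figure D1:**
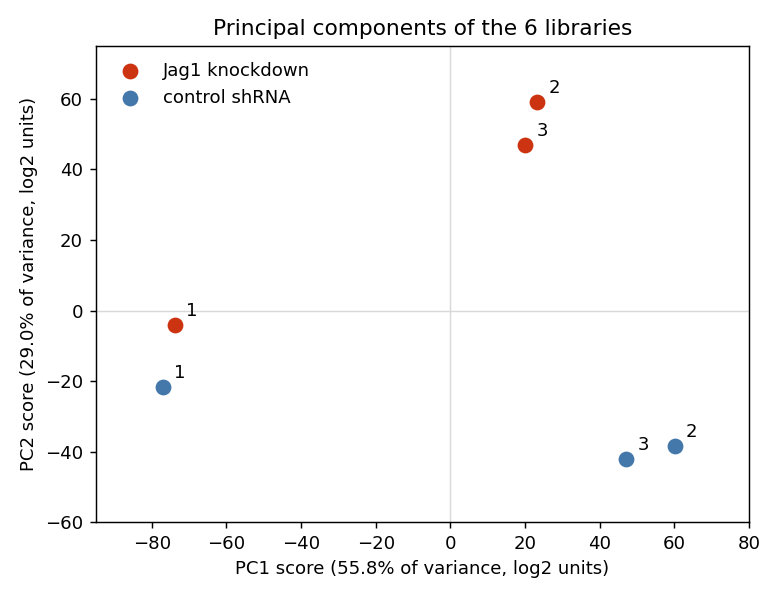
Principal components of the log2 normalised counts of 13997 genes in 6 libraries, with component 1 (55.8% of the variance) on the x axis and component 2 (29.0%) on the y axis, controls in blue and Jag1 knockdowns in red, numbered by replicate. Both replicate 1 libraries lie at the left, at -77.0 and -73.7 on component 1, and the other 4 libraries lie between 20.1 and 60.1.

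Jag1 mRNA was lower in the knockdown library of each pair. Jag1 (ENSMUSG00000027276) lies on the minus strand of chromosome 2 from 137081456 to 137116644 in GRCm38. Its normalised counts were 412, 983 and 847 in controls 1, 2 and 3 and 226, 321 and 557 in knockdowns 1, 2 and 3. Knockdown libraries thus kept 55.0%, 32.6% and 65.8% of the count of the control with the same number, and the group means of 747 ± 298 and 368 ± 170.4 gave 49.2%. The groups overlapped, since knockdown 3 lay above control 1. The limma log2 change was -1.03 (SE 0.45), with an adjusted p of 0.691 in limma, 0.693 in edgeR and 0.451 in DESeq2. An exact two-sided permutation test gave p = 0.2, where 3 against 3 libraries cannot go below 0.1, and an exact sign-flip test over the pairs gave p = 0.25, the smallest that 3 pairs allow. With the replicate number as a term, the change was -1.02 (SE 0.27, adjusted p = 0.00628) in DESeq2, and the adjusted p was 0.149 in limma and 0.182 in edgeR. Without pair 2 or pair 3 the adjusted p of DESeq2 with this term was 0.785 and 0.0858.

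By DESeq2 with the replicate term, epithelial genes such as Cldn4, Rab25 and Epcam were higher in the knockdown. Transcription factors that repress them, Zeb1, Zeb2 and Snai2, were lower. In limma the adjusted p of these named genes ran from 0.604 to 0.746 without that term and from 0.136 to 0.149 with it. None of them passed edgeR, with or without the term. Genes of cell division, of glycolysis and the hypoxia response, of cholesterol synthesis, and of both the classical and the basal-like PDAC subtypes were higher as groups, and Wnt targets were lower, by camera with a preset correlation in limma. None of these lists passed with an estimated correlation or with fry, and the division, cholesterol and basal-like lists were near 0 in pair 1 (medians 0.07, 0.07 and 0.08). Cd9 itself and the targets of Notch signalling did not pass the tests. Of the 24 gene lists tested by camera, 8 were higher and 2 lower at an adjusted p below 0.05, and 11 were called in the blocked fit, where YAP targets were added. With a correlation between genes estimated from the data, and with fry, 0 of the 24 lists were called.

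No single gene passed limma, which called 0 higher and 0 lower, with 1021 genes at an unadjusted p below 0.05 and a smallest adjusted p of 0.604, and edgeR likewise called 0 and 0 with 1021 genes at an unadjusted p below 0.05. With the replicate number as a term, limma and edgeR each called the same 2 genes, both higher, of which 1 was Cyp2s1, a cytochrome P450. Cyp2s1 (chromosome 7, 25802475 to 25816913, minus strand) went from 405 ± 326 to 3330.4 ± 2920.2 normalised counts, a log2 change of 2.88 in limma, with adjusted p of 0.0178 in limma and 0.0239 in edgeR with the replicate term. DESeq2 called 101 genes higher and 73 lower without the replicate term, and 640 higher and 361 lower with it, of which 392 and 182 changed by over 2-fold. Of all 13997 tested genes 42.0% changed in the same direction in all 3 pairs, against 25% for unrelated pairs. Pairs 2 and 3 correlated at r = 0.74 across genes, which raises this share by itself, so the excess does not show that pair 1 agreed. In 11.7% of the genes the groups did not overlap, against 10% by chance.

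Counts depended on the libraries used. In limma without control 1 the count was 210 higher and 84 lower, and without knockdown 1 it was 1 higher, Sprr2a3, and 0 lower. In limma on replicates 2 and 3 only, which leaves out both libraries that stand apart, 846 genes were higher and 500 lower, and 712 of these 1346 were among the 1001 genes of DESeq2 with the replicate term. Without pair 2, DESeq2 with the replicate term called 97 genes, of which 92 were among the 1001. Without pair 3 it called 127, with 122 among the 1001, and without pair 1 it called 2120, with 917 among them. The share of mitochondrial reads was lower in the knockdown of each pair, by more in pairs 2 and 3 (0.595%, 1.55% and 2.03% in controls 1, 2 and 3, and 0.555%, 1.02% and 1.20% in knockdowns 1, 2 and 3). The epithelial and proliferation lists also differ by more in pairs 2 and 3, and whether this share bears on these or other lists was not tested. Single genes below are called by DESeq2 with the replicate term, a fit chosen after limma had called none. On simulated data this fit made 33 false calls, beside 76 and 99 recovered genes of the smaller and the larger change. That is a larger share of false calls than its threshold allows, and limma and edgeR with the term made 6 each. Some of the single genes named below may thus be false calls. The simulation, with changes alike in every pair, does not give their share.

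Epithelial genes had the smallest adjusted p of the 24 lists. The median log2 change of the 30 tested members was 1.14 (camera adjusted p = 1.18e-17 in limma, adjusted p = 0.221 with an estimated correlation), and the medians in pairs 1, 2 and 3 were 0.46, 1.55 and 1.41. In DESeq2 20 of these genes rose, 0 fell and 10 did not pass. Adjusted over the list alone, limma called 19 higher and 0 lower, and DESeq2 with the replicate term called 25 and 0. Cldn4, a claudin of tight junctions, rose by 2.81 (SE 0.39, adjusted p = 3.99e-10 in DESeq2) from 1270.3 ± 774 to 8531 ± 4736 normalised counts. The adhesion molecule Epcam rose by 1.37 (SE 0.29, adjusted p = 2.77e-04 in DESeq2) from 5251 ± 2445 to 13384 ± 5131. Rab25, a GTPase of apical recycling, rose by 2.46, the adaptor subunit Ap1m2 by 3.06, the transcription factor Ovol1 by 2.93, and the keratins Krt8 and Krt19 by 1.08 and 1.44, with DESeq2 adjusted p from 2.21e-07 to 0.0171. E-cadherin (Cdh1) did not pass at 0.53 (SE 0.19, adjusted p = 0.0674 in DESeq2), nor did Krt7 at 0.55 (adjusted p = 0.0776).

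Mesenchymal genes were lower as a list, with a median log2 change of -0.78 over 19 members (camera adjusted p = 0.00333 in limma, adjusted p = 0.666 with an estimated correlation) and pair medians of -0.58, -0.69 and -0.52. In DESeq2 7 of these genes fell, 1 rose and 11 did not pass. Adjusted over the list alone, limma called 1 lower, Cdh2, and DESeq2 with the replicate term called 9 lower and 2 higher, S100a4 among the higher. Zeb1, a repressor of epithelial genes, fell by 1.21 (SE 0.22, adjusted p = 7.20e-06 in DESeq2) from 677 ± 361 to 293 ± 159.7 normalised counts. Zeb2 and Snai2, related repressors, changed by -2.47 and -2.44, the receptor tyrosine kinase Axl by -2.31, N-cadherin (Cdh2) by -1.20, Emp3 by -0.78 and moesin (Msn) by -0.53, with DESeq2 adjusted p of 4.01e-10 for Axl and at most 0.0288 for the others. Axl also followed the replicate number, with 157 and 64.0 in control 1 and knockdown 1 against 13204 and 10164 in controls 2 and 3. Vimentin (Vim) was at -0.48 (SE 0.23, adjusted p = 0.239 in DESeq2). The list lost its call without control 2 (median -0.31, adjusted p = 0.094), without knockdown 1 (median -0.26, adjusted p = 0.321) and with a filter at 50 normalised counts (adjusted p = 0.0873), each by limma and camera.

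Partial EMT genes, which encode laminins, integrins and matrix proteases, were not called as a list in limma and camera (median 0.35 over 19 members, adjusted p = 0.106). They passed as higher by camera with edgeR (adjusted p = 0.0294, and 0.00402 with the replicate term) and with DESeq2 (adjusted p = 0.00687 without the replicate term and 3.80e-04 with it). In limma and camera they passed as higher with a filter at 50 (median 0.49, adjusted p = 0.0055) and with spike-in scaling (adjusted p = 0.0108). They also passed on replicates 2 and 3 only (adjusted p = 0.0417) and without control 2 (adjusted p = 0.00604). Without knockdown 1 they passed too, with a median of 0.73 (adjusted p = 1.01e-04). With an estimated correlation in limma they did not pass (adjusted p = 0.948). By gene, the laminin chain Lamb3 rose by 3.62 and the urokinase receptor Plaur by 0.77, with DESeq2 adjusted p of at most 0.00217, while Cdh13 (-0.97), Emp3 and Snai2 fell. The integrin Itgb1 stayed at 0.03 (SE 0.16). Adjusted over the list alone, limma called 2 higher, Lamb3 among them, and 0 lower, and DESeq2 with the replicate term called 7 and the 3 lower genes above.

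**Figure D2:**
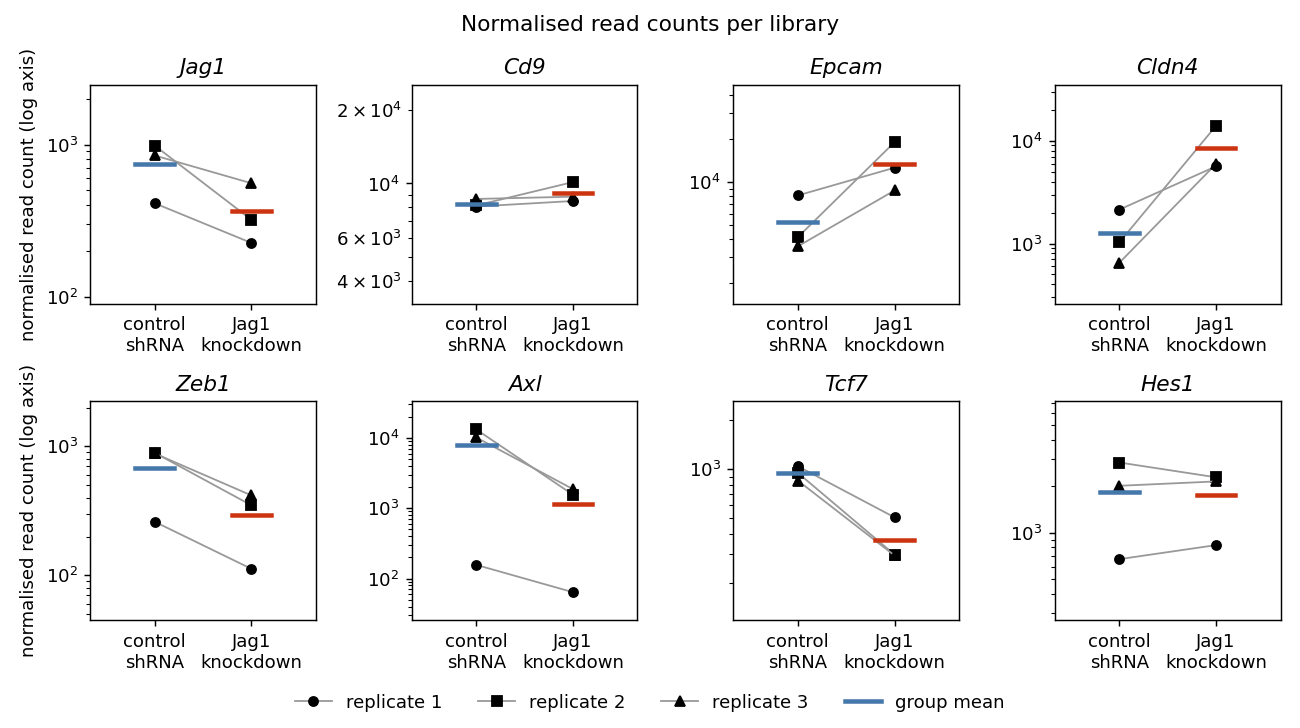
Normalised counts (log axis) of Jag1, Cd9, Epcam, Cldn4, Zeb1, Axl, Tcf7 and Hes1 in 3 control and 3 Jag1 knockdown libraries, with markers for the replicate number, lines that join the same number and bars at the group means (control blue, knockdown red). Cldn4 is higher and Jag1, Zeb1 and Tcf7 are lower in the knockdown of every pair, Cd9 stays between 8046 and 10135, and Axl in replicate 1 lies far below the other replicates.

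Cd9 stood at 8272 ± 323 normalised counts in controls and 9146 ± 874 in the knockdown, a log2 change of 0.14 (SE 0.17, adjusted p = 0.727 in DESeq2), and with scaling by spike-in reads its limma change had the opposite sign, -0.06. That scaling moved the median change of all genes to -0.19. The tumour-initiating cell list was not called (median -0.18 over 17 members, camera adjusted p = 0.479 in limma). In DESeq2 4 of its members fell and 0 rose: the kinase Dclk1 by -1.80, the R-spondin receptor Lgr5 by -1.38, the RNA-binding protein Msi2 by -0.78 and the hyaluronan receptor Cd44 by -0.64 on the log2 scale, with adjusted p of 0.00705, 0.0224, 0.00771 and 0.00488. The receptor Met was added, as higher, by adjusting over the list alone. The surface markers Prom1 and Tspan8 were at -0.25 (SE 0.30) and 0.21 (SE 0.18). The tetraspanin list, which includes Cd9, was not called (median 0.03 over 22 members, adjusted p = 0.772 in limma and camera). Among them Tspan1 rose by 3.87 (adjusted p = 0.012 in DESeq2) and Cd53, best known from leukocytes, fell by 1.25 (adjusted p = 0.00289).

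The Notch pathway itself showed no list shift. Notch targets had a median log2 change of -0.06 over 8 members (camera adjusted p = 0.964 in limma), with a mean of -0.01 and the direction of camera's statistic positive, and 0 members were called. Notch components other than Jag1 had a median of -0.07 over 24 members (adjusted p = 0.849). Hes1, a direct target, was at 1852 ± 1106 and 1759.7 ± 809 normalised counts (log2 change 0.03, SE 0.21), and its sign differed between pairs, at 0.30, -0.32 and 0.09, and under edgeR, DESeq2 without the replicate term and spike-in scaling. The targets Nrarp, Dtx4 and Notch3 were at -0.45, -0.96 and 0.38, the receptors Notch1 and Notch2 at -0.45 and -0.15, the ligands Jag2 and Dll1 at 0.32 and -0.86, and the processing enzymes Adam10 and nicastrin (Ncstn) at 0.29 and 0.21, none of which passed DESeq2, with adjusted p from 0.131 to 0.724. Rbpj, the DNA-binding partner of the Notch receptors, fell by 0.58 (SE 0.17, adjusted p = 0.0151 in DESeq2), the 1 member of the 24 that was called. Dll4 was too low for the filter and Hey1 is not listed in the table.

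Genes of both PDAC subtypes were higher. The classical list had a median log2 change of 0.69 over 26 members (camera adjusted p = 8.72e-06 in limma, adjusted p = 0.142 with an estimated correlation) and pair medians of 0.27, 0.87 and 0.60. In DESeq2 9 members rose, 1 fell and 16 did not pass. Ctse rose by 1.75, Myo1a by 1.74, Krt20 by 1.44, the cadherin Cdh17 by 1.29 and the galectin Lgals4 by 0.98. Their DESeq2 adjusted p ran from 7.74e-05 to 0.0464, the highest that of Ctse, which changed by -0.39 in pair 1. Agr2, a protein disulfide isomerase of mucous cells, changed by -1.30 (adjusted p = 6.54e-05 in DESeq2). Adjusted over the list alone, limma called 5 higher (Anxa10, Cldn18, Cdx2, Myo1a and Ceacam1) and 0 lower, and DESeq2 with the replicate term 12 higher and 2 lower, Agr2 and Muc6. The basal-like list had a median of 1.17 over 13 members (camera adjusted p = 6.50e-05 in limma, adjusted p = 0.571 with an estimated correlation) and pair medians of 0.08, 1.11 and 1.20. Without knockdown 3 its median was 0.66, and with a filter at 50 normalised counts 0.63. Of its members 4 rose and 9 did not pass. Those that rose were the cornified envelope gene Sprr1a by 3.08 (adjusted p = 9.77e-18 in DESeq2), Krt15 by 2.87, the p53 and p63 target Perp by 0.76 and the glucose transporter Slc2a1 by 0.63. With that adjustment limma called 0 of them and DESeq2 with the replicate term 6 higher and 1 lower, Scel.

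Ductal markers were not called as a list (median 0.07 over 16 members, camera adjusted p = 0.209 in limma). In DESeq2 Krt19, the mucin Muc1 (0.98), the transcription factor Pdx1 (0.75) and Slc9a3r1 (0.57) rose, and the chloride channel Cftr fell by 0.74 (adjusted p = 0.00308). Krt7 and Car2 were added as higher and Spp1 as lower by adjusting over the list alone. Osteopontin (Spp1) went from 151719 ± 112723 to 23041 ± 8996 normalised counts, a log2 change of -2.25 that did not pass DESeq2 with the replicate term (adjusted p = 0.0846). Spp1 passed DESeq2 without that term (-2.72, adjusted p = 0.0217) and limma on replicates 2 and 3 only (-3.14, adjusted p = 0.00686). Tuft cell markers were not called (adjusted p = 0.943 by camera in limma), and their median of 0.18 and mean of -0.07 over 6 members differ in sign. Dclk1 was the 1 tuft marker that fell, and Avil and Ptgs1 were at 0.35 and 0.28.

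Wnt targets were lower, with a median log2 change of -0.49 over 13 members (camera adjusted p = 0.00215 in limma, adjusted p = 0.221 with an estimated correlation) and pair medians of -0.41, -0.75 and -0.68. In DESeq2 6 members fell, 0 rose and 7 did not pass. Tcf7, a transcription factor of the pathway, fell by 1.41 (SE 0.23, adjusted p = 5.95e-07 in DESeq2) from 949 ± 95.9 to 367 ± 121 normalised counts. Lgr5, Tnfrsf19 (-1.01), the ubiquitin ligase Znrf3 (-0.81), Cd44 and cyclin D1 (Ccnd1, -0.49) fell as well. Adjusted over the list alone, limma called 1 lower, Tcf7, and DESeq2 with the replicate term called 7 lower. The list missed the threshold without control 1 (median -0.76, adjusted p = 0.0656 in limma and camera).

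Genes of DNA replication and mitosis were higher, with a median log2 change of 0.75 over 34 members (camera adjusted p = 2.27e-08 in limma, adjusted p = 0.666 with an estimated correlation). This was so in pairs 2 and 3, with medians of 1.19 and 1.07, and was near 0 in pair 1, with a median of 0.07. Without control 1 the median was 1.22, and on replicates 2 and 3 only it was 1.13. In DESeq2 16 members rose, 0 fell and 18 did not pass, and adjusted over the list alone 21 rose, against 0 in limma. The mitotic kinase Plk1 rose by 1.30 (SE 0.35), Cdc20 by 1.29, Ccnb2 by 1.28, survivin (Birc5) by 1.27 and Mki67 by 1.09, with DESeq2 adjusted p from 0.00173 to 0.0122. Top2a, at 0.72 (adjusted p = 0.0643 in DESeq2), did not pass, but did in limma on replicates 2 and 3 only (1.06, adjusted p = 0.0265).

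Glycolysis and hypoxia genes were higher in all 3 pairs, with pair medians of 0.43, 0.90 and 0.47 and a median log2 change of 0.65 over 22 members (camera adjusted p = 4.57e-06 in limma, adjusted p = 0.666 with an estimated correlation). The median was 0.38 without control 1 and 0.31 without knockdown 2. In DESeq2 13 members rose, 0 fell and 9 did not pass, and adjusted over the list alone 16 rose, against 0 in limma. Ndrg1 rose by 2.11 (SE 0.24, adjusted p = 5.37e-15 in DESeq2), adrenomedullin (Adm) by 3.58, Ankrd37 by 1.50, the prolyl hydroxylase Egln3 by 1.48, lactate dehydrogenase A (Ldha) by 0.70 and enolase (Eno1) by 0.52.

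Cholesterol synthesis genes were higher, with a median of 0.45 over 22 members (camera adjusted p = 4.25e-06 in limma, adjusted p = 0.666 with an estimated correlation) and pair medians of 0.07, 0.86 and 0.54. The median was 0.71 without control 1 and 0.26 with spike-in scaling. By DESeq2 2 members rose and 0 fell, Lss by 0.82 and Acat2 by 0.69 (adjusted p = 0.0484 and 0.0225), whereas Srebf2 was at 0.25. By adjusting over the list alone 7 rose in DESeq2 and 0 in limma. NRF2 targets were called higher with a small median, 0.20 over 19 members (camera adjusted p = 0.0384 in limma, adjusted p = 0.666 with an estimated correlation), and pair medians of 0.02, 0.40 and 0.31. Their call was lost without control 2 (median 0.01, adjusted p = 0.246), without knockdown 1 (0.0868) or knockdown 3 (0.149), with quantile normalisation (0.0516), DESeq2 without the replicate term (0.0699) and spike-in scaling (0.1). The median rose to 0.43 without control 1 and 0.31 without knockdown 2. Heme oxygenase (Hmox1) rose by 1.41, Gsta4 by 0.94, Me1 by 0.78 and Taldo1 by 0.65, and the cystine transporter Slc7a11 changed by -1.38, with DESeq2 adjusted p from 0.00115 to 0.0363, while Tkt and Gsr were at 0.48 and -0.14. With adjustment over the list alone 6 rose and 1 fell in DESeq2, and limma called 0.

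**Figure D3:**
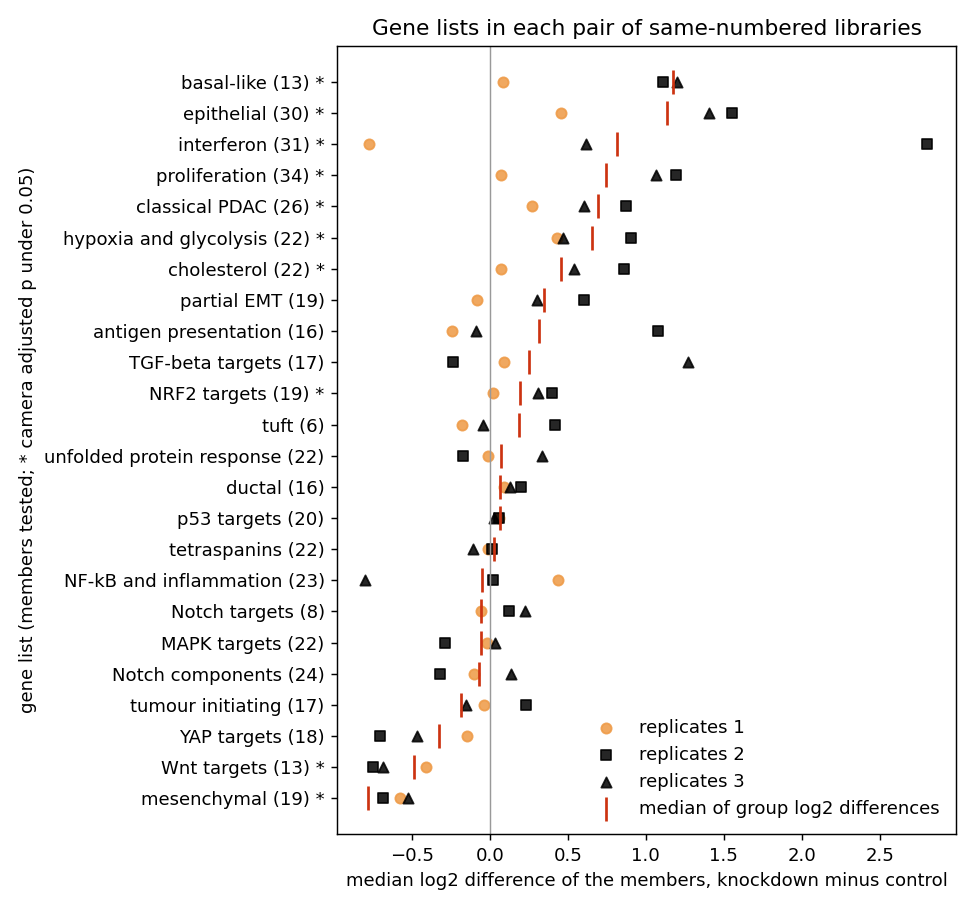
Median log2 difference between knockdown and control over the members of each of 24 gene lists, with a marker for each of the 3 pairs and a red tick for the median of the group changes, and an asterisk where camera's adjusted p with the preset correlation is below 0.05. The epithelial list lies above 0 in each pair and the Wnt and mesenchymal lists below 0 in each pair, and the interferon list runs from -0.78 in pair 1 to 2.80 in pair 2.

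Interferon-stimulated genes differed between pairs. Their median log2 change was 0.82 over 31 members (camera adjusted p = 1.39e-05 in limma, adjusted p = 0.72 with an estimated correlation), but the pair medians were -0.78 in pair 1, 2.80 in pair 2 and 0.61 in pair 3. Without control 2 the list was not called (median 0.26, adjusted p = 0.136), and its median was 1.63 without control 1 and 0.53 without knockdown 2. In DESeq2 with the replicate term and without pair 2 it turned to -0.09 (adjusted p = 0.291 by camera). The leukocyte marker Cd68 rose from 136 to 988 in pair 2, 111 to 400.4 in pair 3, and 98.6 to 117 in pair 1, where the interferon list fell. Cd14, also a leukocyte marker, fell from 7938 to 4309 in pair 2 and 9085 to 3211 in pair 3, and rose from 874 to 1944 in pair 1. Coro1a rose in each pair but stayed at or below 64.0. A link was not tested. No member of the interferon list passed DESeq2 with the replicate term or limma, over all genes or adjusted over the list alone. Bst2 and Oas2, the most abundant members, were at 0.09 (SE 0.26) and 1.01 (SE 0.80). Antigen presentation genes were not called (median 0.32 over 16 members, adjusted p = 0.132 by camera in limma), with H2-K1 and H2-D1 at 0.57 and 0.62. They passed as higher on replicates 2 and 3 only (median 0.64, adjusted p = 0.0359) and without control 1 (median 0.64, adjusted p = 0.0056). Without knockdown 3 they passed as higher too (median 0.57, adjusted p = 0.00393). With an estimated correlation they did not pass (adjusted p = 0.948).

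NF-kB and inflammation genes were not called (median -0.05 over 23 members, camera adjusted p = 0.59 in limma). They passed as lower on replicates 2 and 3 only (adjusted p = 0.0417), without control 1 (adjusted p = 4.31e-04) and without knockdown 2 (adjusted p = 0.0363), but not with an estimated correlation (adjusted p = 0.963). Lipocalin 2 (Lcn2) stood at 721, 26822 and 37036 normalised counts in the controls and 2600.4, 2185 and 1040.0 in the knockdowns, and its log2 change of -2.84 (SE 1.60) did not pass DESeq2 with the replicate term (adjusted p = 0.336). Lcn2 passed DESeq2 without that term (-3.47, adjusted p = 0.0296) and limma on replicates 2 and 3 only (-4.39, adjusted p = 0.00581). The chemokine Cxcl5 was at -0.96 (SE 0.87) and passed limma on replicates 2 and 3 only (-1.88, adjusted p = 0.00659), and Tnfaip3, an inhibitor of NF-kB, was the 1 member that rose, by 0.95 (adjusted p = 0.00623 in DESeq2). Nfkbia rose as well when adjusted over the list alone.

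Targets of 3 further signalling pathways were not called by limma and camera: TGF-beta (median 0.25 over 17 members, adjusted p = 0.462), YAP (median -0.33 over 18, adjusted p = 0.479) and MAPK (median -0.06 over 22, adjusted p = 0.508). YAP targets were called lower in the blocked fit (adjusted p = 0.027), with spike-in scaling (adjusted p = 0.036) and without control 1 (adjusted p = 0.0056), and TGF-beta targets higher with spike-in scaling (adjusted p = 0.0212), without control 2 (adjusted p = 0.014) and without knockdown 1 (adjusted p = 0.00697). With the replicate term in edgeR and DESeq2, camera called TGF-beta targets higher (adjusted p = 0.00655 and 0.001) and YAP targets lower (adjusted p = 0.00908 and 0.00463). MAPK targets were called lower without control 1 (adjusted p = 0.0319). With an estimated correlation none of the 3 lists passed camera in limma (adjusted p = 0.963 for each, and 0.649 for YAP targets in the blocked fit). Among TGF-beta targets the integrin chain Itgb6 (2.30) and Smad6 (1.54) rose and the matricellular protein Ccn2 fell by 1.57 (adjusted p = 0.0017 in DESeq2), and Bhlhe40 was at 0.92. Among YAP targets Ccn2, Axl, the ectonucleotidase Nt5e (-1.27) and Igfbp3 (-0.86) fell and Gadd45b (0.90) rose, and Myof and tissue factor (F3) were at 0.28 and 0.88, where F3 passed limma on replicates 2 and 3 only (1.41, adjusted p = 0.0158). Among MAPK targets Ccnd1 and Ier3 (-0.94) fell, and Epha2 was at 0.39. When adjusted over each list alone, DESeq2 with the replicate term called 5 TGF-beta targets higher (with Smad7 and Bhlhe40 added) and 1 lower, 2 YAP targets higher (F3 and Gadd45b) and 5 lower (with Crim1 added), and 1 MAPK target higher (Areg) and 6 lower, and limma called 0.

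The unfolded protein response and p53 target lists were not called (medians 0.07 and 0.06 over 22 and 20 members, adjusted p = 0.508 and 0.972 by camera in limma). In DESeq2 the stress-induced transcription factors Atf3 and Ddit3 rose by 1.02 and 0.85, and the p53 target Pmaip1 rose by 1.05 (adjusted p = 0.00759). Over the list alone it was joined by Cdkn1a, Gdf15 and Gadd45a, all higher. The chaperones Hspa5 and Calr were at 0.40 and 0.27, and Tnfrsf10b and Bax at -0.38 and 0.06.

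The largest changes in DESeq2, among called genes with groups that did not overlap, were increases of genes that were low in the controls. Sprr2a3, a small proline-rich protein with near-identical neighbours, rose by 5.11 (SE 0.77, adjusted p = 3.27e-08) from 67.5 ± 21.9 to 3391 ± 2577 normalised counts. Lypd8, Gsta1, AA467197, Prap1, Tdpoz4, Fam3b, Cited1, Enpp3, the epithelial interferon Ifne, Tspan1 and Teddm3 rose by 3.85 to 5.58, with adjusted p of at most 0.012 in DESeq2. Prap1 went from 14.2 ± 3.01 to 778 ± 977 normalised counts and Tspan1 from 256 ± 378 to 1325 ± 290.3. In the other direction Igfbp4, which binds insulin-like growth factors, fell by 3.12 (SE 0.90, adjusted p = 0.0121) from 8202 ± 5199.6 to 871 ± 384. The retinol transporter Stra6 fell by 2.18 (SE 0.37, adjusted p = 1.81e-06) from 9684 ± 1939 to 2429 ± 1561. Angptl2 (-2.59), the cationic amino acid transporter Slc7a2 (-2.84), Lgi2 (-2.83), C1qtnf1 (-2.65), Ism1 (-2.65), Zeb2, neuregulin 1 (Nrg1, -2.45), Runx3 (-2.41), Cavin2 (-2.32) and Nckap5l (-2.06) also fell, with adjusted p of at most 0.0499.

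Few markers of other cell types were tested. Of the fibroblast, immune and endothelial lists 10 genes were tested, and their median lay between 22.4 and 80.4 normalised counts in all 6 libraries. The abundant ones were complement C3 (2437 to 8647 in controls, 1088 to 4205 in knockdowns), Cd14 (874 and 1944 in replicate 1, 3211 to 9085 in the other 4 libraries) and the VEGF receptor Flt1, none called by limma or by DESeq2 with the replicate term. Cd68 rose, from 115 ± 18.8 to 502 ± 444 normalised counts, and Esam, an endothelial adhesion molecule, fell from 69.2 ± 66.2 to 33.4 ± 51.6, with DESeq2 adjusted p of 0.00794 and 0.043. Esam was highest in both replicate 1 libraries, at 144 and 93.0. The other tested markers, Pdgfra and Pdgfrb of fibroblasts, Coro1a of leukocytes, Tek and Eng of endothelium, Bhlha15, Amy1 and Cela1 of acinar cells and Isl1 of endocrine cells, stayed at or below 102 normalised counts in each library and were not called by limma or DESeq2.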

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

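In this part, 3 tests were chosen after the results they measure had been seen: the levels of markers of other cell types, the Jag1 reduction of pair 1 and the interferon medians per pair. The grouping of replicate 1 against replicates 2 and 3 was also drawn from these data, and the replicate numbers are treated as pairs by their correlation alone.

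A test of the interaction between the knockdown and the replicate in limma found 8 genes whose difference in pair 1 was unlike that in pairs 2 and 3, with adjusted p from 0.0438 to 0.0486 and 1596 genes at an unadjusted p below 0.05. Pair 1 holds 1 library per group in this test, and its spread is assumed to be that of the other libraries. Of these, Ly6g, rose in pairs 2 and 3 by 8.15 and 7.80 on the log2 scale and changed by -0.11 in pair 1. The other 7 rose in pair 1 and fell in pairs 2 and 3, among them Igfbp1 (1.43, -6.98 and -6.15 in pairs 1, 2 and 3), Trf (1.27, -4.49 and -4.84), Itih2 (1.04, -4.48 and -4.61), Cp (0.40, -3.57 and -4.06), Rbp4 (0.72, -3.42 and -3.70) and Selenop (1.87, -1.92 and -1.85). These genes were singled out after their values were seen.

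The ERCC spike-ins, which entered no test of genes, took 1.04% of the reads in knockdown 2, above the highest control share of 0.711%. The other libraries held 0.529%, 0.668% and 0.711% in the controls and 0.740% and 0.462% in knockdowns 1 and 3, so the shares did not follow the group. A spike-in share moves with the amount of RNA in a library as with the amount of spike-in added, and the 2 cannot be told apart here, since the amounts are not given in the labels.

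The first pattern weighed is the distance of both replicate 1 libraries from the other 4, with 2062 genes higher and 1681 lower in replicates 2 and 3 in limma. Depth was tested by thinning the gene reads of each library to 22110664, after which 3485 genes were called against 3743 before, 3318 of them shared, which argues against depth as the cause. RNA of fibroblasts, leukocytes or endothelial cells stays open, since only 3 of 14, 3 of 15 and 4 of 12 markers were tested. The highest median of 1 of these lists was 988 normalised counts (leukocytes, knockdown 2), which is the value of Cd68 alone. Cd14 stood at 874 and 1944 in replicate 1 against 3211 to 9085 in the other 4 libraries. A difference in culture or library batch between replicate 1 and the others stays open too. The labels do not say what the number stands for, and no biological explanation was tested.

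The second pattern is the smaller difference in pair 1, where the SD of the log2 difference across genes was 0.473, against 0.923 and 0.862 in pairs 2 and 3. A weaker reduction of Jag1 in pair 1 stays open: the log2 ratio of Jag1 was -0.86 in pair 1, weaker than -1.61 in pair 2 and stronger than -0.60 in pair 3, and with 1 library per group in each pair the spread of these ratios is not known. A candidate explanation is the starting state of control 1, which may already lie part of the way towards the knockdown libraries of replicates 2 and 3. Across genes, control 1 minus control 2 correlated with knockdown 3 minus control 3 at r = 0.361. Control 1 minus control 3 correlated with knockdown 2 minus control 2 at r = 0.425. These differences share no library, but controls 2 and 3 correlated at r = 0.99, so both subtract nearly the same profile. A positive r can arise from that alone, so these values cannot decide whether control 1 lies towards the knockdowns. The starting state is a hypothesis from the data that it explains, and it does not separate a biological state from a technical one.

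The third pattern is the interferon list, called higher in the knockdown by camera. A swing of knockdown 2 stays open: the list was still called without that library (adjusted p = 0.00905 by camera in limma, median 0.53), but that call assumes a correlation of 0.01 between genes where 0.844 was estimated, and control 2 lay farther from the mean of the libraries (list median -1.65) than knockdown 2 (1.06). The list median was -0.78 in pair 1, against 2.80 in pair 2 and 0.61 in pair 3, and with 1 library per group in each pair this does not settle whether the list rises in every pair. The list was no longer called without control 2 (adjusted p = 0.136), without both libraries of pair 2 in DESeq2 with the replicate term (median -0.087, adjusted p = 0.291) or with an estimated correlation in limma (adjusted p = 0.72). The difference between pairs of this list was not tested, and its cause stays open.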

How the results depend on the processing

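Chosen after the data were seen were the fits with a replicate term in DESeq2 and edgeR, the DESeq2 fit of these without a pair, limma on replicates 2 and 3 only, the term for replicate 1, the blocked fit with an estimated correlation, and spike-in scaling. Every alternative fixed in advance was run. The values below are log2 changes for genes and median log2 changes for lists, and the cause of a change was not tested unless one is given.

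Jag1 was lower under all 24 alternatives, with log2 changes from -1.41 to -0.73 and adjusted p from 0.00288 (DESeq2) to 1.00 (limma). It passed the threshold under 2 of them, DESeq2 with the replicate term (-1.02) and the same without pair 1 (-1.11, adjusted p = 0.00288). For 16 of the alternatives fixed in advance gene values were given. Of 126 other named genes, 113 kept their direction under each of these that tested them, and 13 did not. The filter at 50 tested 111 of the 126. Pseudocounts of 0.5 and 5, median centring and limma without a trend changed no call and no direction of a named gene or list.

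The number of genes called followed the tool and the libraries. It was 0 higher and 0 lower in limma and in edgeR, each with 1021 genes at an unadjusted p below 0.05, and DESeq2 without the replicate term called 101 higher and 73 lower (93 and 58 by over 2-fold). In limma with the replicate block and in edgeR with it, 2 genes were higher and 2 of them by over 2-fold. In limma the replicate block changed no other call of a list or named gene except that of YAP targets (adjusted p = 0.027 by camera). In edgeR and in DESeq2 with the block, partial EMT (adjusted p = 0.00402 and 3.80e-04), TGF-beta (0.00655 and 0.001) and YAP targets (0.00908 and 0.00463) were called by camera. With the replicate term DESeq2 called 640 higher and 361 lower (392 and 182 by over 2-fold), limma on replicates 2 and 3 only 846 and 500 (661 and 359), and limma with spike-in scaling 66 and 31 (66 and 31). The DESeq2 fit with the replicate term called 1250 and 870 genes without pair 1 (778 and 438 by over 2-fold), 62 and 35 without pair 2 (62 and 35), and 88 and 39 without pair 3 (88 and 36). Leaving out 1 library at a time in limma gave 0 to 210 genes higher, 0 to 84 lower, 0 to 210 higher by over 2-fold and 0 to 83 lower by over 2-fold, the highest counts without control 1. A group left with 2 libraries is assumed to vary like the other.

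List calls depended on the list test. With an estimated correlation, with fry, and with the replicate block and an estimated correlation, 0 lists were called, 0 higher and 0 lower. Without the block the estimate was -0.0016 for classical genes and -0.0022 for Wnt targets, below the preset 0.01. A higher correlation thus does not account for the loss of these calls in that fit. For the other called lists the estimate ran from 0.0755 (NRF2 targets) to 0.895 (proliferation). The cause was otherwise not tested. The epithelial, classical, basal-like, proliferation, hypoxia and cholesterol lists were called under all of the other 24 of 27 alternatives, and Wnt targets under 23, interferon genes under 22, mesenchymal genes under 21 and NRF2 targets under 18. Their adjusted p by camera or fry ran from 1.07e-34 to 0.684 for epithelial genes, from 6.81e-09 to 0.649 for classical, from 1.16e-09 to 0.684 for basal-like, from 2.76e-24 to 0.684 for proliferation, from 1.96e-22 to 0.666 for hypoxia and from 8.09e-10 to 0.684 for cholesterol genes. They ran from 8.24e-07 to 0.649 for Wnt targets, from 3.88e-12 to 0.773 for interferon, from 6.62e-05 to 0.666 for mesenchymal and from 0.00635 to 0.684 for NRF2 targets. Called under some alternatives only were partial EMT (12 of 27, adjusted p down to 1.82e-07), YAP (9, 0.00139), TGF-beta (7, 4.03e-10), antigen presentation (5, 0.00105), NF-kB (4, 4.31e-04), MAPK (1, 0.0319) and unfolded protein genes (1, 0.00814), and the other 7 lists under none. With a filter at 50 the lists called lower fell to 1, with fewer genes tested, in DESeq2 without pair 1 they came to 4, and without 1 library to 1 to 4.

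Some directions changed. Without a filter Notch components were at 4.72e-04. Tetraspanins were at -0.0024 with a filter at 50, -0.0024 with quantile normalisation, -0.026 with edgeR and -0.020 with DESeq2. Hes1 was at -0.072 with edgeR and -0.072 with DESeq2. On replicates 2 and 3 only, Avil was at -0.013, Hes1 at -0.11 and Notch targets at 0.026. With spike-in scaling, which moved the median change of all genes to -0.19, Bax was at -0.14, Bst2 at -0.10, Cd9 at -0.055, Hes1 at -0.17 and Itgb1 at -0.17, and among lists ductal was at -0.13, tuft at -0.0057, p53 at -0.13, unfolded protein at -0.12, NRF2 at -3.02e-04 and tetraspanins at -0.17. That shift is as large as or larger than each of these 11 values. In DESeq2 with the replicate term and without pair 1, Avil was at -0.019, Hes1 at -0.12 and Notch targets at 0.022. Without pair 2, Bst2 was at -0.26, Notch components at 0.055, interferon at -0.087, antigen presentation at -0.12, MAPK at 0.079 and tetraspanins at -0.018. Without pair 3, Hes1 was at -0.0025, Itgb1 at -0.016, Prom1 at 0.19, NF-kB at 0.14, TGF-beta at -0.11, unfolded protein at -0.048 and tetraspanins at -0.025.

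Leaving out 1 library at a time in limma reversed more directions, and in 10 cases the lowest value came without control 1 and the highest without knockdown 1. These were Avil (-0.90 to 1.23), Epha2 (-0.20 to 1.21), Hes1 (-0.59 to 0.50), Jag2 (-0.077 to 0.80), Myof (-0.12 to 0.89), Nt5e (-2.997 to 0.52), and the p53 (-0.15 to 0.21), NF-kB (-0.65 to 0.31), YAP (-0.87 to 0.31) and MAPK lists (-0.42 to 0.60). The others were Itgb1 (-0.084 to 0.19), Prom1 (-0.68 to 0.15), Bax (-0.10 to 0.19), Bst2 (-0.12 to 0.33), Cxcl5 (-2.88 to 0.20), Notch3 (-0.14 to 1.26) and Ptgs1 (-0.041 to 0.80). Lists that did so were tumour-initiating (-0.23 to 0.15), TGF-beta (-0.30 to 1.00), unfolded protein (-0.22 to 0.20), Notch components (-0.24 to 0.041), tuft (-0.034 to 0.38) and tetraspanins (-0.051 to 0.14).

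Depth was tested only on the comparison of replicate 1 with the others in limma, where thinning to 22110664 gene reads per library kept 3318 of the 3743 genes called. The knockdown tests were not repeated on thinned reads. Genes with fewer than 61 reads over the 6 libraries were not in the table, so nothing can be said of genes below that level. Hey1 was not listed, and the filter is not stated.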

Other observations

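In this part, the comparison of replicate 1 with replicates 2 and 3, the genes named for it, the list of genes of the 2-cell embryo and the count of splits for genes called by limma were chosen after the data were seen. The labels do not say what the replicate number stands for, so the comparison describes 2 libraries against 4 and not a group of the study.

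Some genes were abundant in both replicate 1 libraries and low in the other 4. Muc6 stood at 4186 and 2414 normalised counts in control 1 and knockdown 1 and at no more than 58.5 in the other 4 libraries. Olfm4 stood at 12203 and 7921 against no more than 77.2, Spdef at 5442 and 3598 against 87.2, Ern2 at 872 and 711 against 17.6, and Muc2 at 1127 and 1082 against 116. Ankrd1 ran the other way, at 277 and 488 against at least 9881 in the other 4, as did Ccn1 at 116 and 151 against at least 3684, Plat at 254 and 234 against at least 6125, and Cxcl5 at 719 and 1554 against at least 12453. All of these passed limma with adjusted p from 4.54e-04 to 0.00387.

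Lists differed between the same libraries by camera in limma. Higher in replicates 2 and 3 were YAP targets (median log2 difference 1.82, adjusted p = 5.75e-09), NF-kB and inflammation (1.76, 1.08e-07), MAPK targets (1.27, 1.26e-07), hypoxia and glycolysis (1.04, 2.47e-06), TGF-beta targets (1.80, 1.01e-04), mesenchymal (1.35, 1.45e-04), partial EMT (1.26, 1.80e-04), p53 targets (0.65, 0.0274) and the unfolded protein response (0.53, 0.0394). Lower were proliferation (-0.90, 1.82e-10), cholesterol synthesis (-0.55, 3.78e-04), interferon (-0.90, 0.009) and antigen presentation (-0.84, 0.0178). With an estimated correlation none of the 24 lists passed, the lowest adjusted p being 0.139.

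The tested genes of the 2-cell mouse embryo, except Usp17la, were higher in knockdowns 2 and 3 than in the other 4 libraries. Usp17la stood at 125 and 147 in controls 2 and 3 and 89.7 and 99.3 in knockdowns 2 and 3. Of 32 listed genes 15 were tested, and DESeq2 with the replicate term called 10 of them higher and 0 lower. The median over the 15 was 11.6, 0 and 0 normalised counts in controls 1, 2 and 3 and 11.4, 54.1 and 53.5 in knockdowns 1, 2 and 3. Several of these genes were listed at 0 in controls 2 and 3, so no fold is given. By camera in limma the unadjusted p was 2.03e-13, and 2.12e-07 with the replicate block, whereas with an estimated correlation it was 0.0712. The list was drawn up after some of its members had been seen, so these p describe it and do not test it. Apart from Usp17la, the tested genes lay below 10 normalised counts in controls 2 and 3. They could thus pass the filter only through knockdown 2 or 3, which partly fixes the direction. Most belong to families of near-identical copies, so their reads cannot be given to single genes with certainty, and the named gene Tdpoz4 is one of them.

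The 6 libraries can be split into 2 groups of 3 in 10 ways, which are too few for a share under 0.05. In limma the real split gave 0 genes, so 10 of 10 splits reach that count whatever they give and nothing follows from it. The highest of the others was 0, with 1021 genes at an unadjusted p below 0.05 in the real split and 2889, 2734 and 1339 in the 3 splits with more, the same as those named below. For lists called by camera 7 of 10 splits gave as many, with 10 lists in the real split and 12 in the highest other. In DESeq2 without the replicate term it was 4 of 10, with 174 genes in the real split and 1083 in the highest other. The splits that gave more genes were control 1 with both knockdowns 1 and 2 (1083), with knockdowns 1 and 3 (799), and controls 1 and 3 with knockdown 1 (264). All 3 keep the replicate 1 libraries together, but so does controls 1 and 2 with knockdown 1, which gave 76. A count several times the real one points to a structure of the samples, whose cause was not tested.

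Of the 10 splits 4 part all 3 pairs, which is again too few for a share under 0.05. DESeq2 with the replicate term called 1001 genes in the real split, and 1 of 4 splits reached that count, the real one. The other 3 gave 0, 0 and 95. Limma in the blocked fit gave 2725 genes at an unadjusted p below 0.05 in the real split and 184, 26 and 1206 in the others, and 11 lists against 6, 4 and 9.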
